A study of Homo sapiens with 15 samples.

How the data were processed

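The samples were libraries of RNA fragments crosslinked to Ago2, the Argonaute protein that carries miRNAs to their target mRNAs, prepared by HITS-CLIP. In this assay ultraviolet light links the protein to RNA in living cells, the complex is precipitated with an antibody, and the bound RNA is sequenced. The cells were T-REx-293, an established derivative of the human embryonic kidney line HEK293. Per the labels, 15 libraries fell into 3 groups of 5: a control siRNA named gl3.1 and 2 siRNAs against HuR, named dsiHuR2 and dsiHuR5. HuR is the RNA-binding protein encoded by ELAVL1, which binds U-rich and AU-rich elements. Cells received 3 successive transfections 2 days apart. Per the labels' protocols, 2 of the 5 replicate sets used 100 nM siRNA with TransIT-TKO and 3 used 25 nM with calcium phosphate. Transfection method and dose thus changed together between replicate sets and not between groups.

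One deposited table covered the whole series and held 4699 peaks with 1 line each. The submitters' processing notes name Bowtie2, TopHat, DESeq2 and the human build hg19, without versions or roles. The peak caller, its threshold, whether reads were pooled before peaks were called, and which of the HuR siRNA libraries entered the HuR siRNA values are not given in the sources used here. Each peak had 2 signal values in the deposited table, the authors' mean normalized counts in control and in HuR siRNA libraries, named per the file headers after the base mean of DESeq2. The deposited log2 fold change is of HuR siRNA over control, per the file headers, and it is not the log2 ratio of both deposited means. Its sign differed from that ratio in 389 of the 4450 peaks where both were above 0, and the absolute log2 fold change of these 389 was at most 0.62. The deposited p-value of each peak came with an adjusted p-value for 417 peaks only. The deposited FPKM was 1 value per gene, always above 1, with no statement of the RNA libraries behind it. A deposited ratio equalled the control mean divided by the FPKM in all 4699 peaks within 1e-06. The deposited table also marked peaks that overlapped a HuR site, peaks on a 3' UTR with a HuR site anywhere, and peaks with a 7mer miRNA site. The source of the HuR sites and the miRNA families behind the 7mer mark are not given in the sources used here.

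No value per library was in the table used here. The number of reads per library is therefore unknown, and no replicate spread, standard error or test between libraries was computed. The planned fits of HuR knockdown, of each HuR siRNA alone and of both HuR siRNAs against each other needed such values and were replaced by a description of the authors' own test. All peaks were classed by the authors as 3' UTR exon, so the planned counts per transcript region and of 3' UTR against coding sequence were not made. The table had no peak score, and the stricter peak set in the alternatives held peaks at least as wide as the median of 44 nt.

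Coordinates are those of the deposited table, in hg19, with 1 added to the start so that positions count from 1. Near the start of chromosome 9, where both builds number bases alike, 10 peaks were matched by sequence, and in all 10 the first base lay 1 after the start in the table. Flanking sequence was taken by matching each peak's sequence to 3' UTRs of GENCODE v29, an annotation of another build whose coordinates are not printed. A single exact match was found for 4473 peaks (95.2%) in 2539 genes. Gene names were matched to the same annotation for 2647 of 2653 names.

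Seed matches were counted in windows of 51 nt around the peak midpoint. Each window was paired with 1 window of the same width 200 nt upstream or downstream, drawn at random, and both flanks had to lie in the same 3' UTR, which left 3084 peaks. The site was the 7mer complementary to miRNA bases 2 to 8. Shares were compared with an exact two-sided McNemar test and adjusted by the Benjamini-Hochberg method over 27 families, 19 picked as abundant in HEK293 cells and 8 picked as not expressed there. HuR motifs were compared in the same windows, and differences between peak classes in motif share were permuted and resampled over windows. The 3084 windows came from 1808 genes, and the McNemar test took them as independent. Windows and flanks of neighbouring peaks in one 3' UTR can overlap, so these p-values can overstate the evidence. Intervals on shares are exact 95% Clopper-Pearson intervals and cover counting error only. The share of list members with a peak was compared with all other protein-coding genes by a two-sided Fisher exact test, adjusted over 12 lists. The lists were known HuR targets, known targets of let-7, of the miR-17 family and of miR-15/16, miRNA machinery, proteins that bind AU-rich elements and 3' UTRs, cell cycle, TGF-beta and BMP signalling, chromatin regulators, cytoplasmic ribosomal proteins, glycolysis and oxidative phosphorylation, markers of tissues the line should lack, and lncRNAs. The last list was not tested, since the table lists 3' UTR peaks only.

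Fold changes and properties of peak classes were averaged per gene and compared by two-sided permutation tests with 100000 permutations, or by sign-flip permutation within 3' UTRs that held both kinds of peak. Intervals on differences are 95% bootstrap intervals from 2000 draws over genes. Mean counts entered as log2(value + 0.5), and control mean over FPKM as log2(ratio + 0.01). Genes and peaks are not independent replicates, so these p-values describe spread across genes within 1 table. A gene list's median log2 fold change was placed among 10000 random lists matched on decile of mean count. Correlations of peak pairs used 10000 permutations within deciles of mean count, and tests of miRNA families 20000. In a scan, each of 8305 7mers held by at least 8 peaks was given the z of the mean log2 fold change of its peaks, with a familywise p from 1000 permutations of the fold changes.

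Groups, gene lists, miRNA families, peak-based tests and their alternatives were fixed before the data were examined. The comparisons of fold change and of motifs between peak classes, the 7mer scan and their alternatives were chosen after seeing the data. Named genes are the 10 with the most peaks, those with the 10 widest peaks, up to 4 members with and 3 without a peak per list, ELAVL1, AGO2 and OIP5-AS1, and the peaks past an adjusted p of 0.05. Some of the genes this rule names are not reported here. Whether both HuR siRNAs moved those peaks the same way cannot be checked from these columns. Other genes named in the text were chosen after their values were seen. On simulated data made from the table, the class test called 4% of shuffled sets over 2653 genes and 94% of sets with a planted log2 difference of 0.1. The 7mer scan made a call in 6% of shuffled sets over 4699 peaks and found a planted shift of 0.9 in 100% of sets. The shift was planted only in 7mers held by well above the fewest peaks allowed, so rarer 7mers and smaller shifts were not tested. These simulations used fewer permutations, and shuffling removed the trend of fold change with mean count. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.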

Results

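Ago2 binding sites were mapped by HITS-CLIP in T-REx-293 cells, a human embryonic kidney line, with and without knockdown of the RNA-binding protein HuR (ELAVL1). The design asked how Ago2 binding to mRNAs differs when HuR is depleted. There were 5 control libraries and 10 libraries with a HuR siRNA, 5 for each of 2 siRNAs. The table used here gave 1 line per peak with the authors' mean over each condition, so no spread between replicates or depth per library can be given. The median peak had an authors' mean normalized count of 1.56 in control and 1.71 in HuR siRNA libraries, and 1728 peaks averaged at least 2 over both conditions.

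The list held 4699 peaks in the 3' UTRs of 2653 genes. They covered 219747 bases, and the median width was 44 nt (25th to 75th percentile 33 to 56 nt). A single peak was listed for 1667 genes, 986 genes had at least 2, and 17 genes had at least 10. Genes with more peaks had somewhat higher FPKM (Spearman's rho across 2653 genes 0.13) and longer 3' UTRs (rho 0.17 across 2642 genes). Each of these permutation p-values was 1e-05, the smallest that 100000 permutations can give, and so was the adjusted value over 3 relations.

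KLHL15, which encodes a substrate adaptor of a cullin ubiquitin ligase, had the most peaks, 26 between positions 24002152 and 24005968 of chromosome X (hg19). GIGYF1, a translational repressor, and BTG2, an antiproliferative gene, had 20 peaks each. INSIG1, which controls sterol synthesis, and NUFIP2 had 16 each. The next were NUCKS1 with 15, the SMAD corepressor SKI with 14, the mRNA-binding protein IGF2BP1 with 13, and the desaturase SCD and cyclin CCND2 with 12 each. All 10 of these 3' UTRs carried a HuR site, and the number of their peaks that overlapped one ran from 1 in BTG2 and NUFIP2 to 9 in NUCKS1. GIGYF1 and BTG2 had summed control means of 114 each at FPKM of only 3.06 and 5.75. NUCKS1, at an FPKM of 85.5, had a summed control mean of 24.9.

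The widest peak, 171 nt, lay in the KLHL15 3' UTR on the minus strand (chromosome X, 24004954 to 24005124). INSIG1 had a peak of 140 nt on chromosome 7 (155100121 to 155100260). SLC38A2, an amino acid transporter, had one of 137 nt, SKI of 136 nt, the ribosomal protein gene RPS16 of 135 nt, the intermediate filament gene VIM of 134 nt, SYNCRIP of 126 nt, IGF2BP1 of 125 nt, and CNBP and ERLIN1 of 122 nt each. Among these 10, RPS16 had the highest authors' mean in control libraries, 11.5, and ERLIN1 the lowest, 1.04.

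Seed matches of most miRNA families picked as abundant in HEK293 cells were concentrated in the peaks. The miR-15/16 site TGCTGCT was present in 4.38% of 3084 peak windows (95% interval 3.68% to 5.16%) and in 1.07% of flanking windows of the same 3' UTRs. The miR-19 site was in 4.21% against 0.681%, the miR-17 family site in 3.76% against 1.04%, the miR-30 site in 3.66% against 0.713%, and the miR-25/92 site in 3.18% against 0.584%. The largest ratio was for let-7, at 1.82% (1.37% to 2.35%) against 0.195%, or 9.33 times, with its site in 6 flank windows. That ratio was 3.78 with 6mer sites, where miR-19 led at 5.34, and 11 with 8mer sites, where miR-26 led at 40. The miR-26 8mer site was in 1.30% of peak windows and only 0.0324% of flanks, so its ratio rests on very few flank windows. Among families with a site in any flank, let-7 stayed first in the other alternatives. It had 3.88 with windows of 50 nt to each side, 18.7 with shuffled windows and 12 among peaks of at least median width. Exact McNemar tests with Benjamini-Hochberg adjustment put 15 of 27 families higher in peaks, and these adjusted p-values ran from 2.8e-19 for miR-19 to 0.043 for miR-7. Of these, 14 were among the 19 families picked as abundant. The other was miR-133, a muscle miRNA and 1 of the 8 picked as not expressed, found in 13 peak windows and 3 flanks (adjusted p = 0.041). The miR-133 call ended with 8mer or 6mer sites, with shuffled windows as background and among peaks of at least median width. Of the abundant families, miR-218 lost its call with 6mer or 8mer sites, with windows of 50 nt to each side and among those wider peaks (adjusted p from 0.060 to 0.83), miR-7 with 6mer sites, the longer windows and the wider peaks (0.48 to 0.96), and miR-196 with 8mer sites (0.11) and the longer windows (0.065). Families that did not pass included miR-21 (0.357% against 0.259%, adjusted p = 0.76) and miR-320 (0.519% against 0.649%, adjusted p = 0.76), which was lower in peaks among the wider ones (0.328% against 1.25%, adjusted p = 0.015). Sites of some families that passed overlap in sequence, such as TTTGCAC of miR-19 and TTGCACT of miR-130, or CTACCTC of let-7 and ACTACCT of miR-196. Their calls are therefore not independent. Windows of one 3' UTR are not independent either, which matters most for calls near the threshold such as miR-7 and miR-133. The authors marked 2115 peaks as holding a 7mer miRNA site. Of the 1462 peaks with a site of the abundant families, 75.8% carried that mark. Only 52.4% of the marked peaks held such a site. For families picked as not expressed, the marked share ran from 25% for miR-122 (8 peaks) to 89.5% for miR-124 (38 peaks). The mark is therefore not limited to families picked as abundant.

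**Figure D1:**
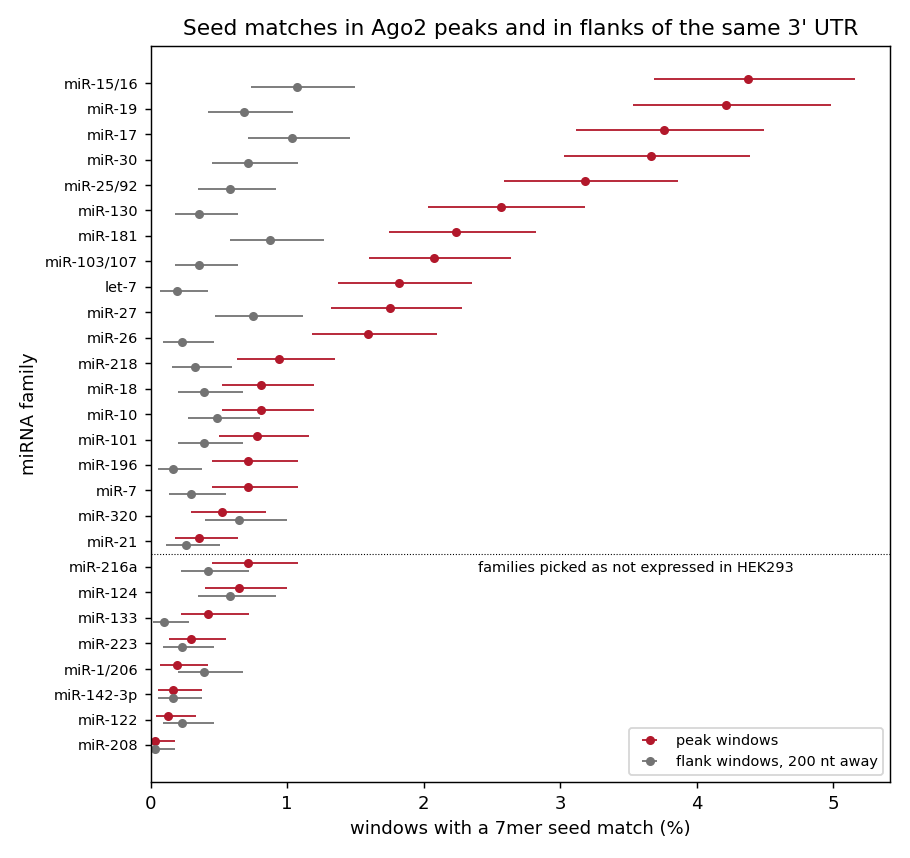
Percent of 51-nt windows with a 7mer seed match for each miRNA family, in peak windows (red) and in windows 200 nt away in the same 3' UTR (grey), with exact 95% intervals over 3084 windows. Families below the dotted line were picked as not expressed in HEK293 cells; miR-15/16, at 4.38% of peak windows, stands highest.

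HuR sites, as marked by the authors, lay on the 3' UTRs of 788 genes (29.7%), which held 1930 peaks (41.1%). A HuR site overlapped 482 peaks in 339 genes, and 1448 further peaks shared a 3' UTR with a HuR site without overlapping it. Peaks with an overlapping HuR site had more Ago2 signal: their median authors' mean in control libraries was 2.38, against 1.48 for the 2769 peaks on 3' UTRs without a HuR site and 1.53 for peaks that only shared the 3' UTR. As gene means of log2(mean count + 0.5), the overlapping class was higher than the class without a HuR site by 0.91 (95% interval 0.76 to 1.08). Their mRNAs had log2 FPKM higher by 1.21 (1.01 to 1.39). Both permutation p-values were 1e-05, the smallest possible. Relative to FPKM, the direction for the overlapping class depended on the summary. The median ratio of control mean to FPKM over peaks was 0.138 for overlapping peaks, below the 0.184 of peaks without a HuR site, and 0.116 for peaks sharing the 3' UTR. As gene means of log2(ratio + 0.01), the overlapping class was above the class without a HuR site by 0.37 (0.099 to 0.65, permutation p = 0.0029, adjusted p = 0.0058 over 14 tests). Peaks sharing the 3' UTR were lower on that scale, at -0.57 (-0.73 to -0.40, permutation p = 1e-05, adjusted p = 2.8e-05). Within 214 3' UTRs that held both kinds, the overlapping peaks had the higher log2 count in 154, with a mean difference of 0.94 (0.74 to 1.13, sign-flip permutation p = 1e-05). A 7mer miRNA site was marked in 45.6% of overlapping peaks (41.1% to 50.2%), 47.4% of peaks sharing the 3' UTR and 43.6% of peaks without a HuR site (41.8% to 45.5%). As means over genes, the share was 49.5% for overlapping peaks and 41.8% without a HuR site, a difference of 7.68 percentage points (2.62 to 12.9, permutation p = 0.0044, adjusted p = 0.0078). Peaks sharing the 3' UTR were also above those without a HuR site, by 4.41 points (0.752 to 8.15, permutation p = 0.029, adjusted p = 0.041). Within shared 3' UTRs the difference between overlapping and other peaks was 6.02 points (-1.31 to 14.0, permutation p = 0.13, adjusted p = 0.17). As gene means, overlapping peaks were also wider than those without a HuR site, by 2.74 nt (0.53 to 5.01, permutation p = 0.0055, adjusted p = 0.0085). Within shared 3' UTRs the width difference was -1.93 nt (-4.82 to 1.07, sign-flip permutation p = 0.20). The site shares were not matched on width or count.

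AU-rich and U-rich motifs were less frequent at Ago2 peaks than beside them. The pentamer ATTTA was in 7.75% of peak windows and 11.1% of flanks (exact McNemar test, adjusted p = 8.4e-06). TTTTT was in 14.7% against 19.8% (adjusted p = 2.5e-07), and the longer AU-rich heptamers TTTATTT or TATTTAT in 3.08% against 4.38% (adjusted p = 0.0096). Among peaks of at least median width these differences were larger, at -6.69 points in place of -3.37 for ATTTA, -7.81 in place of -5.12 for TTTTT and -3.35 in place of -1.30 for the heptamers. In peaks with an overlapping HuR site, TTTTT was in 22.6% of 301 peak windows and 18.3% of the flanks drawn at random (adjusted p = 0.22), and in 21.6% of both flanks together. The difference between peak and random flank was 7.81 percentage points more positive there than in the class without HuR sites (permutation p = 0.013, adjusted p = 0.040 over 3 motifs). That call ended with the mean of both flanks, chosen after seeing the data, where the difference was 5.04 points (-0.45 to 10.95, permutation p = 0.067, adjusted p = 0.10). For ATTTA, peak minus flank was -3.61 points in the class without HuR sites (exact McNemar test, adjusted p = 9.3e-04) and -3.65 points in the overlapping class, which did not pass (adjusted p = 0.22). The heptamers went the other way in the overlapping class, at 4.98% of peak windows and 2.66% of flanks (exact McNemar test, adjusted p = 0.22). Their difference was 3.26 points more positive there than in the class without HuR sites (permutation p = 0.052, adjusted p = 0.079).

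**Figure D2:**
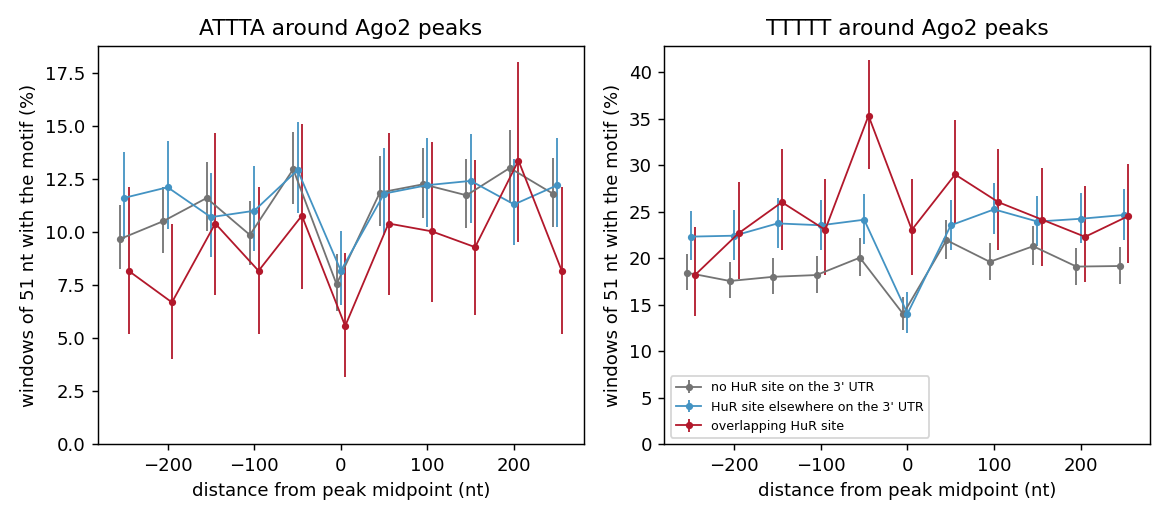
Percent of 51-nt windows with ATTTA (left) or TTTTT (right) by distance in nt from the peak midpoint, for peaks on 3' UTRs with no HuR site (grey), with a HuR site elsewhere on the 3' UTR (blue) and with an overlapping HuR site (red); points are set slightly apart and bars are exact 95% intervals. At the midpoint TTTTT was in 14.0% of windows in the grey and the blue class and in 23.1% in the red class, which had 22.7% at 200 nt upstream, 22.3% at 200 nt downstream and 35.3% at 50 nt upstream.

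Known targets of the miR-17 family, miR-15/16 and let-7 had a peak more often than other protein-coding genes. A peak was listed for 22 of 27 miR-17 family targets (81.5%), 14 of 21 miR-15/16 targets (66.7%) and 13 of 25 let-7 targets, against 13.2% of other protein-coding genes in each case (Fisher exact test, adjusted p = 2.3e-14, 7.1e-08 and 6.3e-06). The cyclins CCND2 with 12 peaks and CCND1 with 9, the transcription factor E2F3 with 8 and TXNIP with 7 led the miR-17 list. LATS2 and RBL1 had none. WEE1 and CDK6, both cell cycle kinases, had 8 peaks each in the miR-15/16 list, from which AXIN2, CARD10 and CCND3 were missing. IGF2BP1 with 13, IGF1R with 9, PRTG with 7 and HMGA2 with 5 led the let-7 list, and ACVR1C, ARID3B and CDC34 had none. Among known HuR targets, 17 of 32 had a peak (53.1%, adjusted p = 2.2e-07). MDM2 had 12, MCL1 11, CCND1 9 and JUN 6, and CCNA2, CCNE1 and CXCL8 none.

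Other regulators were also covered above the other protein-coding genes. Proteins that bind AU-rich elements and 3' UTRs had a peak in 19 of 29 genes (65.5%, adjusted p = 6.4e-10), with IGF2BP1, CELF1 (8 peaks), FMR1 (5) and PTBP1 (4) first and ELAVL3, ELAVL4 and FXR2 without. TGF-beta and BMP signalling had 15 of 26 (57.7%, adjusted p = 2.4e-07), led by SKI, ACVR2B (8), TGFBR3 (4) and TGFBR1 (3); BMPR1A, BMPR1B and INHBA had none. Cell cycle genes had 21 of 40 (52.5%, adjusted p = 1.5e-08), with AURKB, BUB1 and CCNA2 without. Chromatin regulators had 18 of 40 (adjusted p = 1.6e-06), led by SETD5 with 8, ARID1A and EP300 with 4 each and CHD1 with 3, with ASXL1, CHD3 and CHD8 without. In the miRNA machinery 9 of 29 genes had a peak (adjusted p = 0.012): the GW182 proteins TNRC6A and TNRC6C with 8 each and TNRC6B with 6, and the helicase DDX6 with 4. AGO1, AGO2 and AGO3 had none. Glycolysis and oxidative phosphorylation had 10 of 33 (30.3%, adjusted p = 0.011), with PKM (3), ENO1, PGK1 and GPI (2 each) first and ALDOC, ATP5F1A and COX4I1 without. Cytoplasmic ribosomal proteins had 13 of 52 (25.0%, adjusted p = 0.024), among them RPL15 (4), RPS16 and RPL23 (1 each), with RPL10, RPL11 and RPL12 without. Of 30 markers of tissues the line should lack, 1, MBP, had peaks (3.33%, adjusted p = 0.17), while ACTA1, ALB and APOA1 had none. None of 18 lncRNAs, OIP5-AS1, CRNDE, DANCR and EPB41L4A-AS1 among them, was in this list of 3' UTR peaks. The other protein-coding genes include many that the line does not express. Of 12 lists 11 passed, so more frequent peaks were not particular to miRNA targets. With other genes limited to each list's range of 3' UTR length, all 11 calls stayed. The odds ratios were then 18.7 in place of 29 for miR-17 family targets and 9.16 in place of 13.1 for miR-15/16 targets. For let-7 targets it was 5.12 in place of 7.11. With at least 2 peaks required, the glycolysis call ended (adjusted p = 0.093), and the ribosomal proteins fell to 3.85% against 4.94% (adjusted p = 1).

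Few peaks passed an adjusted p of 0.05 with HuR knockdown. ELAVL1 itself had 1 peak, 23 nt on the minus strand of chromosome 19 (8028339 to 8028361, hg19), which overlapped a HuR site. In the authors' deposited table its mean was 1.99 in control and 1.63 in HuR siRNA libraries, with a log2 fold change of -0.19 and p = 0.79. This value is Ago2 binding, and the ELAVL1 mRNA level in each condition was not analysed here. An adjusted p was given for 417 peaks in the authors' deposited table, and 6 of these were under 0.05, 4 higher and 2 lower in HuR siRNA libraries. Under 0.1 there were 18 in the authors' deposited table, 15 higher and 3 lower. At an unadjusted p under 0.05 there were 139 peaks in the authors' deposited table, 94 higher and 45 lower, where 5% of 4699 would be 235. The median log2 fold change over all peaks in the authors' deposited table was 0.06 (25th to 75th percentile -0.31 to 0.44).

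The largest count among the 6 was in LBR, the lamin B receptor. In the authors' deposited table its peak (chromosome 1, 225589537 to 225589573, minus strand, sequence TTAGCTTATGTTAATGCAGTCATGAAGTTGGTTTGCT) rose from a mean of 39.7 to 182, a log2 fold change of 2.36 (adjusted p = 8.0e-04), and it overlapped a HuR site. POM121C, a nuclear pore gene (chromosome 7, 75046921 to 75046948), rose from 0.782 to 10.1 in the authors' deposited table, a log2 fold change of 2.55 (adjusted p = 0.013). SHOC2, a RAS pathway scaffold (chromosome 10, 112772180 to 112772231), rose from 0.936 to 11.3 in the authors' deposited table, with 2.42 (adjusted p = 0.016). The peak in DEGS1, a ceramide synthesis desaturase (chromosome 1, 224380970 to 224381016, sequence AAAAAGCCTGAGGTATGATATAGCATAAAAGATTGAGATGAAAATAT), fell from 59.3 to 7.58 in the authors' deposited table, a log2 fold change of -2.11 (adjusted p = 3.3e-04). CALU, an endoplasmic reticulum calcium-binding protein (chromosome 7, 128409362 to 128409413), had a peak overlapping a HuR site that fell from 21.2 to 3.66 in the authors' deposited table, with -1.97 (adjusted p = 0.011). With the p-values of the authors' deposited table adjusted over all 4699 peaks, 3 peaks passed, of which 2, DEGS1 (adjusted p = 0.0034) and LBR (0.0084), were among the 6, and CALU (0.085), POM121C (0.11) and SHOC2 (0.15) did not pass. The third was in UPF3B, a nonsense-mediated decay factor (chromosome X, 118968215 to 118968236), which had no adjusted p in the authors' deposited table and fell from a mean of 10.6 to 1.76 there, a log2 fold change of -2.15 (adjusted p = 0.041 over all peaks).

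**Figure D3:**
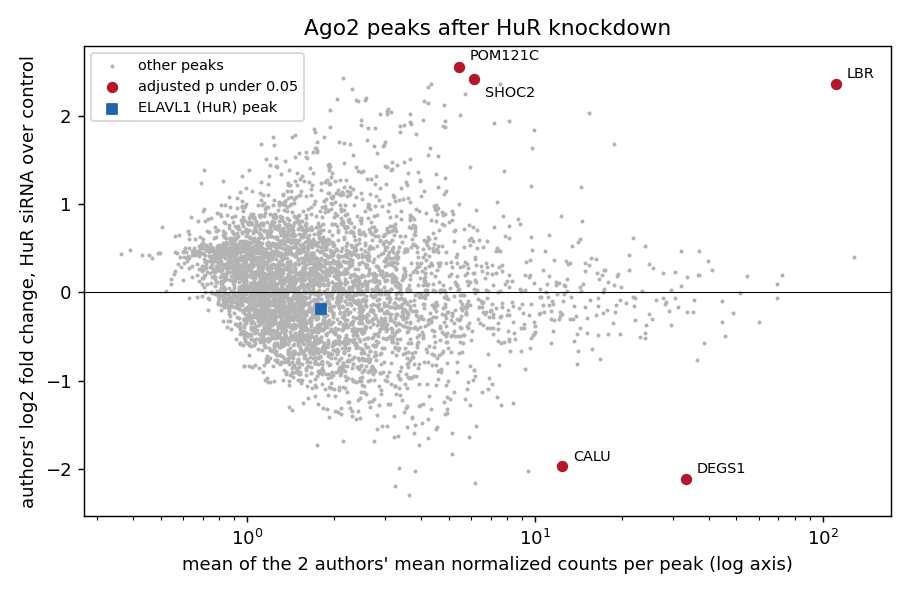
Each point is a peak, with the mean of both authors' mean normalized counts on a log axis and the authors' log2 fold change (HuR siRNA over control) on the vertical axis. Of the 6 peaks with an adjusted p under 0.05, 5 are drawn, in red and named, and the ELAVL1 peak, at -0.19, is a blue square.

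Peaks with an overlapping HuR site had slightly lower fold changes than peaks on 3' UTRs without one. The gene mean log2 fold change was -0.0037 (95% interval -0.055 to 0.049) in 339 genes with overlapping peaks, against 0.095 (0.069 to 0.12) in 1865 genes without a HuR site, a difference of -0.098 (-0.16 to -0.038; permutation p = 0.0022, adjusted p = 0.0051). Peaks sharing a 3' UTR with a HuR site had a mean of 0.055 (difference -0.040, interval -0.086 to 0.0064, permutation p = 0.10, adjusted p = 0.12). Within the 214 3' UTRs with both kinds the overlapping peaks were higher in 100, and the mean difference was -0.075 (-0.15 to 0.0045, sign-flip permutation p = 0.072, adjusted p = 0.12 over 5 tests). The authors' adjusted p was under 0.05 in 2 peaks of each of the 3 classes. These equal counts are not equal rates, since the classes differ in size and in the share of peaks with an adjusted p. An adjusted p was given for 135 of 482 overlapping peaks (28.01%). It was given for 195 of 2769 peaks without a HuR site (7.04%) and for 87 of 1448 peaks sharing the 3' UTR (6.01%). Matching genes on decile of mean count, chosen after seeing the data, moved the difference from the class without a HuR site to -0.025 (-0.095 to 0.046, permutation p = 0.51), and removing decile means moved that within 3' UTRs to -0.029 (sign-flip permutation p = 0.47). Across peaks the log2 fold change fell with mean count (Spearman's rho -0.19), and peaks are not independent replicates.

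Peaks with a 7mer miRNA site had lower fold changes than peaks without one, by -0.044 as gene means (95% interval -0.079 to -0.0053, permutation p = 0.024). Of these genes 563 had peaks of both kinds and entered both groups. The difference was -0.016 (-0.050 to 0.023, permutation p = 0.41) once the mean of each count decile was removed. By miRNA family, on fold changes with that mean removed, none of 22 families with sites in at least 10 genes passed adjustment. The smallest unadjusted permutation p-values were for miR-7, at -0.19 over 37 genes (p = 0.030, adjusted p = 0.50), and miR-130, at 0.097 over 124 genes (p = 0.045, adjusted p = 0.50).

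No gene list moved beyond lists drawn at random. The median log2 fold change of a list's genes in the authors' deposited table ran from -0.071 in cytoplasmic ribosomal proteins (13 genes, percentile 31.6 of 10000 random lists matched on count) to 0.41 in glycolysis and oxidative phosphorylation (10 genes, percentile 95.6). Known HuR targets had 0.084 (17 genes, percentile 62.8), miR-17 family targets 0.084 (22 genes, percentile 65.3), let-7 targets -0.035 (13 genes, percentile 36.1) and miR-15/16 targets -0.0049 (14 genes, percentile 40.5) in the authors' deposited table. The medians in the authors' deposited table were 0.27 for proteins that bind 3' UTRs (19 genes, percentile 94.9), 0.14 for miRNA machinery (percentile 70.6), 0.052 for TGF-beta and BMP signalling (percentile 47.9), 0.017 for cell cycle and -0.052 for chromatin regulators (percentile 26.6). Of all list members 1 had a peak with an adjusted p under 0.05, and 1 peak was called adjusted over the list alone. Within the authors' deposited table all 5 HMGA2 peaks had a log2 fold change below 0 (-0.52 to -0.16) and all 6 TNRC6B peaks one above 0 (0.075 to 0.44), and no adjusted p among these genes was under 0.05.

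A part of the peaks with positive fold changes shared short sequences. Of 8305 7mers tested after the data had been seen, 18 passed a familywise permutation threshold, 16 with higher and 2 with lower fold changes. The 16 fell into 3 groups of overlapping sequences, each given here by its 7mer with the largest z. GCAGTCA, the first of all 16, was held by 61 peaks in 60 genes, with a mean log2 fold change of 0.95 (SD 0.71 over peaks), above 0 in 56. TTCACTA had 30 peaks and a mean of 1.25 (SD 0.87), above 0 in 29. GTGTTCA, whose z of 5.84 was below that of each 7mer in the other groups, had 58 peaks and a mean of 0.52 (SD 0.67), above 0 in 47. The familywise p was 0.001, the smallest that 1000 permutations can give, for GCAGTCA and TTCACTA, and 0.002 for GTGTTCA. AGCGTAA had the lowest z, with a mean of -1.03 (SD 0.72) over 11 peaks, below 0 in 10 (familywise permutation p = 0.001). Among the 94 peaks higher at an unadjusted p under 0.05, 39 (41.5%) held a 7mer that rose, against 4.84% of other peaks (Fisher exact test, p = 2.3e-25). The LBR and SHOC2 peaks were among these, and the DEGS1 peak held GCATAAA, the other 7mer that fell. The UPF3B peak held AGCGTAA, and the POM121C and CALU peaks held none. Within 153 genes that also had a peak without any of the 18, the peaks with a rising 7mer averaged 0.60 and the others 0.042 (sign-flip permutation p = 1e-05, the smallest possible). The 18 were picked on these same fold changes, so that p and the Fisher p overstate the evidence.

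**Figure D4:**
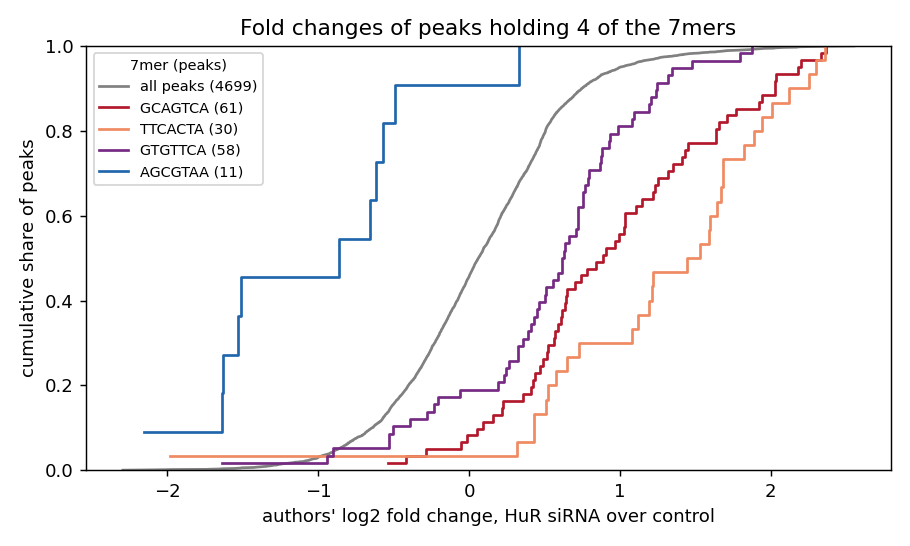
Cumulative share of peaks by the authors' log2 fold change (HuR siRNA over control) for all 4699 peaks (grey) and for peaks holding GCAGTCA (61), TTCACTA (30), GTGTTCA (58) or AGCGTAA (11). The first 3 lie to the right of all peaks and AGCGTAA, with a mean of -1.03, to the left.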

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

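The comparisons of fold change between peak classes and the 7mer scan were chosen after seeing the data, and the tests of the ELAVL1 sequence and of the luciferase siRNA were chosen only after the 7mers were known.

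The 7mers were picked out because their peaks differed from other peaks under the same contrast. The z of the mean log2 fold change was 11.7 for GCAGTCA, 10.96 for TTCACTA and -6.18 for AGCGTAA. In all, 18 7mers passed, 16 of them in 3 groups of overlapping sequences. The seed of a transfected siRNA would need this, but the count of passing 7mers is the flagged pattern itself. Overlapping 7mers share peaks and pass together under any cause tied to a sequence. That test therefore could not tell an siRNA seed from another such cause. The values argue against read depth and GC share as the whole cause. Peaks with a rising 7mer stayed higher by 0.633 matched on depth and by 0.630 matched on GC. Both had permutation p = 1e-05, on 7mers picked from the same values. A change of the whole mRNA is opposed by the mean of 0.042 in other peaks of the same genes. In a random split of the genes, GCAGTCA led the first part with a mean of 1.02 over 36 peaks. It was again higher in the other part, where 24 of 25 peaks were above 0 (difference of gene means 0.78, permutation p = 1e-05). AGCGTAA was lowest in the first part and had only 3 peaks in the other, 1 of them above 0 (difference -1.02, permutation p = 0.0030). A hit of a rising 7mer on ELAVL1 cannot be told apart from chance, since 59.3% of all tested 7mers occur on a strand of its mRNAs. In 3 forms of the search, GCAGTCA occurred 0 times and TTCACTA 1 time on both strands. The forms shifted by 1 base, TGCAGTC and CTTCACT, occurred 0 times on the sense strand and 1 and 3 times on both strands. The shift was made because the base facing siRNA base 1 need not pair. The site of a strand antisense to ELAVL1 would lie on the sense strand, where GCAGTCA and TTCACTA also occurred 0 times. CAGTCAA, of the GCAGTCA group, occurred there 1 time. Whether the rising 7mers come from siRNA strands cut from ELAVL1 was therefore not settled. GTGTTCA, of the third group, was not searched in shifted form. It occurred 2 times on the sense strand, where 38.6% of all tested 7mers and 8 of the 16 rising ones occur. AGCGTAA is the site of bases 2 to 8 of the sense strand of the widely used GL3 luciferase siRNA. It ranked 1 from the lowest among 8305 7mers, so loading of that strand in the control cells is a candidate explanation for its 11 peaks. However, the labels give no sequence for gl3.1, and the site of the antisense strand, TACTTCG, was in 0 peaks. The 19 peaks with the other falling 7mer, GCATAAA, are not covered by either site. Against flanks, AGCGTAA was in 7 peak windows and 1 flank (exact McNemar test, adjusted p = 0.12), TTCACTA in 17 and 9 (0.21) and GCATAAA in 9 and 9. By the same test GCAGTCA was in 40 and 4 (adjusted p = 8.5e-08) and GTGTTCA in 30 and 12 (0.020).

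The class with overlapping HuR sites was picked out because its log2 fold change differed from that of the class without HuR sites, by -0.098. Matched on decile of GC the difference was -0.099 (permutation p = 0.0022). That matching could hardly move it, since mean GC was 43.4% in overlapping peaks and 42.7% in peaks without a HuR site. As gene means, the U share was higher in overlapping peaks by 2.53 points (95% interval 1.48 to 3.62, permutation p = 1e-05). It was not matched, so base composition as the cause stays open. Read depth fits the pattern, since the difference was -0.025 (95% interval -0.095 to 0.046, permutation p = 0.51) matched on depth and the overlapping peaks had higher counts. A change of the whole mRNA cannot be told apart from a change at the site: the difference within shared 3' UTRs was -0.075 (permutation p = 0.072), and peaks sharing the 3' UTR did not differ past the threshold from the class without HuR sites. A biological effect of HuR on nearby Ago2 binding stays open. The depth-matched interval does not bound its size, since it covers spread across genes within 1 table only.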

How the results depend on the processing

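No paired analysis was possible because the table gives the authors' means per condition, with no replicate number. For the same reason the alternatives with a replicate block, a transfection term, other count tools, normalizations, filters or pseudocounts and without each replicate in turn were not run, and those on transcript regions were not run because all peaks were 3' UTR peaks. The alternatives to the fold change comparisons, the 7mer scan, the motif comparison between HuR classes and the authors' adjustment were chosen after seeing the data. Of all alternative values, 120 kept their direction and side of the threshold or stayed within 1.5 times the count, 27 were weaker and 2 reversed. Among those, the number of miRNA families higher in peaks ran from 12 to 17 and that of gene lists from 9 to 11, and the motif differences over all peaks kept their calls, with -6.69, -7.81 and -3.35 points for ATTTA, TTTTT and the heptamers among peaks of at least median width. Among peaks of at least median width 2369 peaks in 1553 genes remained by construction, and 986 genes had at least 2 peaks. Adjustment over all listed peaks gave 3 calls in place of 6, of which 2 were among the 6, and a mean count of at least 2 gave 11 7mers in place of 18 among fewer tested. The difference between peaks with an overlapping HuR site and without a HuR site was -0.025 and -0.011 with matching on depth and with a mean count of at least 2, and -0.057 and -0.0051 over peaks without and with depth matching (permutation p = 0.51, 0.83, 0.051 and 0.88). Within 3' UTRs it turned to 0.0068 among peaks of at least median width (permutation p = 0.92). For TTTTT, peak minus flank, the difference between overlapping peaks and those without a HuR site was 5.04 points with the mean of both flanks (adjusted p = 0.10). The difference by 7mer miRNA site was -0.010 without the 7mer peaks, -0.016 with decile means removed and -0.0040 with a mean count of at least 2 (permutation p = 0.58, 0.41 and 0.91). The log2 odds ratio of ribosomal protein genes turned to -0.38 with at least 2 peaks required. Apart from depth matching and the smaller sets, the cause was not tested. Most peaks averaged fewer than 2 normalized counts, which limits what any single peak can show.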

Other observations

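The genes and the depth trend given here were chosen only after their values were seen. Summed control mean over FPKM was highest for GIGYF1 at 37.2, against a median of 0.28 over 2653 genes, followed by MARCH9 (29.1), MYC (21.4), BTG2 (19.8), SERTAD3 (17.2), ERCC6 (17.1), VLDLR (17.0), MAST4 (16.1), DNAJC27 (15.2) and LMBR1L (12.1). Their median FPKM was 2.47, so a low denominator is part of each ratio. A marked 7mer miRNA site was present in 9 of these 10 genes and in 53.9% of all 2653. These shares are not alike, because sums over peaks favour genes with several peaks, which have more chances to hold a marked site. GIGYF1 and BTG2 had 20 peaks each and MARCH9 and MYC 1 each, while 1667 of the 2653 genes had 1. MYC, a growth regulator and known HuR and let-7 target, had 1 peak (chromosome 8, 128753289 to 128753356, hg19), which overlapped a HuR site. In the authors' deposited table its mean was 110 in control and 146 in HuR siRNA libraries, a log2 fold change of 0.40 with an adjusted p of 0.40.

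Low peaks had the most positive fold changes. In the lowest decile by mean count, the mean log2 fold change was 0.33 and the median 0.38, against -0.027 and -0.087 in the highest. The authors' mean was 0 in control libraries for 230 peaks and 0 in HuR siRNA libraries for 19. There were 5 control and 10 HuR siRNA libraries, so if all entered, a mean of 0 is reached more easily in control. No explanation of the trend with mean count was tested.

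Peaks of one 3' UTR were compared in pairs, with peaks holding one of the 18 7mers left out and fold changes centred and permuted within deciles of mean count. Pairs up to 50 nt apart had correlated fold changes (0.33 over 128 pairs, permutation p = 0.0023, adjusted p = 0.0092 over 4 distances), and pairs 50 to 200 nt apart had 0.098 (801 pairs, p = 0.031, adjusted p = 0.062). Pairs over 200 nt apart had -0.022 (3799 pairs, permutation p = 0.43), consistent with neighbouring peaks sharing reads. Binding that changes over a short stretch of the 3' UTR was not told apart from shared reads by any test here.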
